A study of Mus musculus with 12 samples.

How the data were processed

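Lgr5-GFP+ stem cells of the intestinal epithelium were isolated by FACS from C57BL/6 mice that carried Lgr5-CreERT2-ires-eGFP, and their RNA was sequenced from random-primed cDNA libraries. The mice received 1 tamoxifen injection and then 5 days of tamoxifen diet, and material was taken on day 15. There were 12 libraries, 4 for each of 3 genotypes: Apc+/+ (Apc_WT), ApcFlox/+ (Apc_HET) and ApcFlox/Flox (Apc_KO). The labels number the libraries 1 to 4 within a genotype, state no pairing between numbers, and give no sex, age, batch or date.

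The deposited values are FPKM, per the file headers, which relates fragments to transcript length and to the mapped fragments of the library. The submitters' processing notes name Bowtie, TopHat, Cufflinks and Cuffdiff on mm10 (GRCm38), without versions, annotation or filters, and state no further scaling between libraries. Each table lists assembled loci, 22555 in Apc_WT, 22548 in Apc_HET and 22552 in Apc_KO, of which 3548 name no gene. Of 14499 gene symbols in any table, 295 were left out because their loci differed between the genotypes' tables, 69 of them absent from 1 or 2 genotypes, and 122 because an estimate had failed. The loci of a symbol were summed, which concerned 2693 symbols, and 14082 symbols were used. A symbol that names more than 1 gene, as 296 did, was kept under its joined name. Among the genes of the fixed lists, 8 were lost to differing loci (Aldoa, Cd8a, Fdft1, Hk1, Notch3, Slc16a3, Tgfb2 and Ube2c) and 4 to failed estimates (Ehf, Pfkm and mt-Nd5 among them).

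Symbols were matched to the annotation through RefSeq identifiers. Of 12944 symbols with one, 12821 were in the gene table, and 13799 symbols had 1 annotated gene on the same chromosome. The share of the annotated gene that the deposited locus spans was computed and is given where a named gene falls under 80%. Coordinates are on GRCm38.

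Genes were kept with at least 1 FPKM in at least 4 of the 12 libraries, which left 12962. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with lmFit, contrasts.fit and eBayes with a trend, in 1 fit of all 12 libraries. Tests were two-sided, p was adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The 3 comparisons were Apc_KO minus Apc_WT, Apc_HET minus Apc_WT and Apc_KO minus Apc_HET. Fold changes are on the log2(FPKM + 1) scale, so they understate the ratio of genes near 0 FPKM.

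There were 28 lists with 577 genes, fixed before the data were examined, as were the comparisons, the tests and the first group of alternatives named at the end. Of these genes, 489 were found, 3 under an older symbol (Clca1 as Clca3, Siglecf as Siglec5, Msmo1 as Sc4mol). The lists cover intestinal stem cells, Wnt targets, Wnt pathway components, Paneth, goblet, enteroendocrine and tuft cells, enterocytes, intestinal transcription factors, the Notch pathway, S phase and mitosis, DNA methylation machinery, Polycomb, nucleolus and polyamine genes, glycolysis, cholesterol synthesis, fetal-like and regenerative genes, p53 targets and cell cycle inhibitors, BMP and TGF-beta, MHC class II, interferon response, immediate early and heat shock genes, leukocytes, stroma and endothelium, erythrocytes, proximal small intestine, ileum and colon, and mitochondrially encoded genes. Lists with at least 5 kept genes, 26 of them, were tested with limma's camera at its preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The erythrocyte list and the mitochondrially encoded list had 0 kept genes and were not tested.

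Named genes were chosen by a rule fixed at the same time. It took, among called genes whose genotypes did not overlap and whose higher group averaged at least 5 FPKM, without predicted models and small RNAs, the 6 of largest positive and the 6 of largest negative fold change. From each list it took up to 2 called members for Apc_KO against Apc_WT and up to 1 for each other comparison. Where a comparison called no gene it took the 3 in each direction with the smallest unadjusted p, as values that did not pass. In a list with no called member, the 2 members of highest mean FPKM could be given as values. Apc, Lgr5, Axin2 and Dnmt1 are given in every genotype. Genes outside the rule are marked as named after their values were seen. Some genes that the rule picked are withheld and not given.

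Apc was compared by an exact two-sided permutation test of mean log2(FPKM + 1), 4 libraries against 4, with 70 regroupings and a smallest possible p of 0.0286. The effects of the 2 genotypes were related across genes with the Apc_WT libraries divided into separate pairs, over 6 splits, so that the effects shared no control. Beside them 20 simulations were run without any change and with independent noise for each gene. The procedure was tested on simulated data with 200 changed genes per comparison, 100 of each size. The changed genes lay above a minimum level in Apc_WT, and the noise was independent between genes and libraries. For Apc_KO against Apc_WT it recovered 81 of 100 genes of log2 size 1 and 97 of 100 of size 2, with 5 false calls, and for Apc_HET against Apc_WT 85 and 96, with 12 false calls.

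The files give no counts, so the absolute depth is unknown and no counting interval can be given. A relative depth was read from the ratios of the steps between FPKM values, where at least 9 of a library's 11 pairs agreed to within 0.1 on the log2 scale. Alternatives tried were a pseudocount of 0.1, no low-value filter and one of 5 FPKM, median-of-ratios size factors, quantile normalization, fits of only the 2 genotypes compared, the replicate number as a block, robust eBayes, limma's arrayWeights, a 2-fold minimum, and leaving out each library in turn. Added after the data were seen were the highest locus of each symbol, failed estimates kept, loci of at least 80% of the gene, an exact permutation test of list medians per library, and the slope without each library. Further tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.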

Results

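RNA levels were measured as FPKM in Lgr5-GFP+ intestinal stem cells from 4 Apc_WT, 4 Apc_HET and 4 Apc_KO mice. Apc encodes a scaffold of the complex that marks beta-catenin for destruction in the Wnt pathway, and the floxed allele loses it after Cre recombination. Total FPKM per library ran from 391710 in Apc_KO replicate 1 to 518428 in Apc_KO replicate 4. Relative to Apc_WT replicate 1, depth was 0.371, 0.624 and 0.529 in Apc_WT replicates 2, 3 and 4, 0.871, 0.785, 0.737 and 0.883 in Apc_HET replicates 1 to 4, and 0.483, 0.432 and 0.607 in Apc_KO replicates 1, 3 and 4. That of Apc_KO replicate 2 was undetermined and the absolute depth is unknown. The correlation of log2 values within a genotype ran from 0.913 to 0.981 across genes, and the first principal component held 63.9% of the variance. Size factors ran from 0.953 to 1.06 and differed by genotype. They were 0.953 to 0.964 in Apc_WT, 1.01 to 1.02 in Apc_HET and 1.01 to 1.06 in Apc_KO.

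Apc itself lies on chromosome 18 from 34220924 to 34322552, and its locus in the tables spans 99.7% of the gene. Its level was 8.89 ± 1.64 FPKM (SD, n = 4) in Apc_WT, 11.0 ± 1.11 in Apc_HET and 13.8 ± 3.18 in Apc_KO. The log2 difference was 0.58 for Apc_KO against Apc_WT (exact permutation p = 0.0857), 0.29 for Apc_HET against Apc_WT (exact permutation p = 0.0857) and 0.28 for Apc_KO against Apc_HET (exact permutation p = 0.171). With size factors the differences were 0.47 (exact permutation p = 0.0857), 0.22 (exact permutation p = 0.2) and 0.25 (exact permutation p = 0.286) in the same order. In the limma fit Apc was called higher in Apc_KO than in Apc_WT (adjusted p = 0.0142). The tables hold 1 value for the whole gene and none for its exons, so the deletion itself was not measured. Without Apc_KO replicate 4 the difference from Apc_WT was 0.71 and that from Apc_HET 0.42, each at the smallest exact permutation p the design allows, 0.0286.

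The comparison of Apc_KO with Apc_WT asks what loss of both Apc copies did to gene expression in these cells. Notum, a secreted Wnt inhibitor that the pathway switches on, rose from 0.233 ± 0.119 to 303 ± 49.9 FPKM (SD, n = 4), a log2 fold change of 7.93 (SE 0.13, adjusted p = 5.8e-12). Sox17, a transcription factor of endoderm, rose from 0.0121 ± 0.0106 to 106 ± 19.7 FPKM, and the homeobox gene Msx1 from 0.261 ± 0.114 to 97.5 ± 17.3. Olfm4, a marker of small intestinal stem cells, fell from 5461 ± 340 to 391 ± 343 FPKM, with a log2 fold change of -4.42 (SE 0.65, adjusted p = 0.000151). Gip, an incretin hormone gene, fell by 4.64 on the log2 scale, and Vdr, the vitamin D receptor, fell by 3.95, from 175 ± 12.6 to 12.3 ± 8.18 FPKM.

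Among 12962 genes tested, 5904 were called, 3613 higher and 2291 lower, and 1535 and 1033 of these by at least 2-fold. Of all genes, 40.4% had no overlap between the genotypes' libraries, against 2.86% by chance. The median log2 fold change was 0.12, and scaling moved it together with the balance of calls. With size factors it was 0.01, with 2890 genes higher and 2807 lower, and with quantile normalization -0.02, with 2764 higher and 3043 lower. The other genes with the largest rises were Wfdc18 (6.44), Ctse (5.92) and Gbx2 (5.78), and those with the largest falls were Slc1a1 (-8.10), Arg2 (-4.42), Sst (-4.40) and Car4 (-4.40), all as log2 fold changes. The locus of Slc1a1 spans 11.8% of the gene, that of Ctse 36.6% and that of Olfm4 59.2%.

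Most Wnt target genes rose. Of 25 measured, 19 rose, 0 fell and 6 did not pass, and 19 were called when adjusted over the list alone; the list median was 1.53. Axin2, a feedback inhibitor of the pathway, rose from 49.6 ± 6.29 to 128 ± 21.4 FPKM (log2 fold change 1.34, adjusted p = 1.04e-05). Camera called the list higher (adjusted p = 1.89e-10), with adjusted p = 0.319 with an estimated correlation. Wnt pathway components went both ways, 9 higher, 5 lower and 13 not passing (16 called when adjusted over the list alone), and the list was not called (camera adjusted p = 0.638). The ligand gene Wnt11 rose by 1.94 and the receptor gene Fzd3 by 1.67 on the log2 scale, the locus of Fzd3 spanning 46.9% of the gene.

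Stem cell markers went both ways: 11 of 23 rose, 6 fell and 6 did not pass, with 17 called when adjusted over the list alone. Camera did not call the list (median 0.54, adjusted p = 0.46), whereas fry called it higher. Its median per library, as log2(FPKM + 1), was 6.05, 5.56, 5.92 and 5.10 in Apc_KO replicates 1 to 4 and 4.98, 4.89, 4.94 and 4.75 in Apc_WT (two-sided exact permutation p = 0.0286, the smallest possible, and 0.0531 adjusted over lists). Igfbp4 rose from 31.4 ± 6.43 to 261 ± 28.4 FPKM while Olfm4 fell as above. Lgr5, the receptor gene whose reporter defined the sort, was 23.8 ± 4.35 FPKM in Apc_WT and 65.4, 35.4, 36.3 and 27.0 in Apc_KO replicates 1 to 4 (log2 fold change 0.70, adjusted p = 0.0272). The Lgr5 call ended with size factors (0.58), quantile normalization (0.64) and in a fit of only the 2 genotypes, and without Apc_WT replicate 2 (0.70), 3 (0.62) or 4 (0.66); without Apc_KO replicate 1 the value was 0.45.

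**Figure D1:**
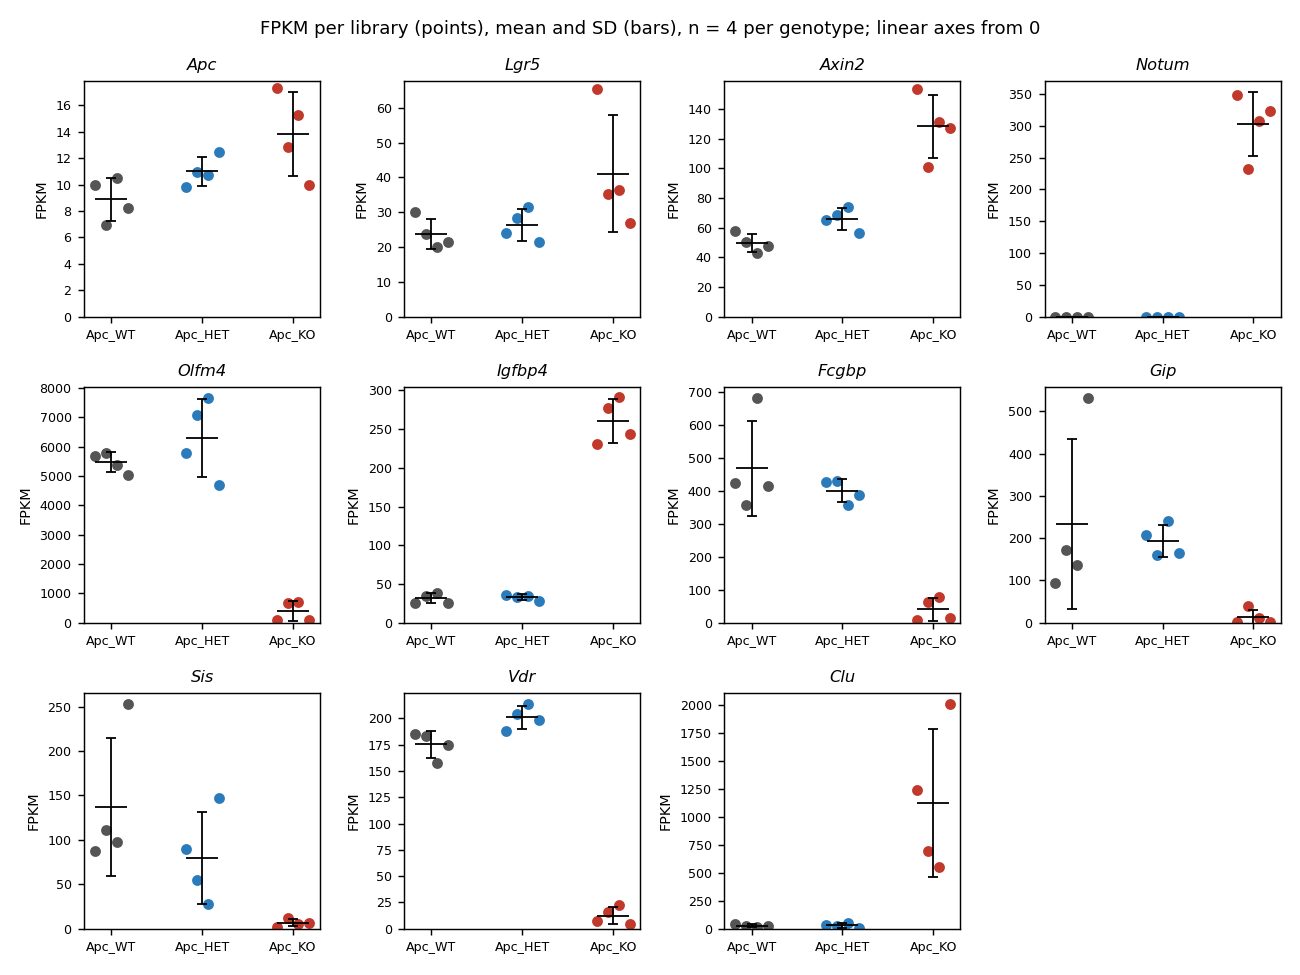
FPKM of 11 genes in each library (points) of Apc_WT, Apc_HET and Apc_KO, with the mean and SD (bars, n = 4) on linear axes from 0. Notum averaged 303 FPKM in Apc_KO against 0.233 in Apc_WT, and Olfm4 391 against 5461.

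Genes of differentiated cells fell. Of 30 enterocyte genes 29 fell, 0 rose and only Cubn (locus 49.0% of the gene, named after its value was seen) did not pass, with 29 called when adjusted over the list alone. The list median was -2.68, and the brush-border disaccharidase gene Sis fell from 137 ± 77.8 to 6.61 ± 3.86 FPKM (log2 fold change -4.20, adjusted p = 4.1e-05). Cyp3a11, a drug-metabolising enzyme gene, fell by 4.16 on the log2 scale. Camera called the list lower (adjusted p = 1.51e-15), with adjusted p = 0.319 with an estimated correlation. Intestinal transcription factors were 14 lower, 4 higher and 3 not passing (19 called when adjusted over the list alone), with Vdr and Creb3l3 (-2.52, locus 58.6% of the gene) lowest (camera adjusted p = 0.000227, and adjusted p = 0.319 with an estimated correlation).

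Most goblet, enteroendocrine and tuft cell genes were lower as well, and a smaller share of Paneth cell genes. Of 19 goblet cell genes 15 fell and 2 rose (18 called when adjusted over the list alone), with Fcgbp, a mucus protein gene, falling from 469 ± 145 to 40.5 ± 34.5 FPKM and Clca3 lower by a log2 fold change of -4.14. Apc_KO replicates 1 to 4 read 9.0, 61.9, 77.7 and 13.4 FPKM for Fcgbp, 0.421, 17.8, 24.0 and 2.70 for Clca3 and 0, 5.00, 5.37 and 0.0867 for Sst, an enteroendocrine gene. The goblet cell genes Retnlb (0.93) and Foxa3 (0.94), named after their values were seen, rose. Of 29 enteroendocrine genes 24 fell, among them Sst and Gip, and Pcsk1n (1.40, locus 74.5% of the gene, named after its value was seen) rose (26 called when adjusted over the list alone). Of 17 tuft cell genes 14 fell, while Avil, an actin-binding protein gene, rose by 2.77 (15 called when adjusted over the list alone). Camera called goblet (adjusted p = 9.3e-07), enteroendocrine (adjusted p = 2.91e-09) and tuft (adjusted p = 1.71e-05) lists lower, each with adjusted p = 0.319 with an estimated correlation. Of 13 Paneth cell genes 5 fell, 1 rose and 7 did not pass (9 called when adjusted over the list alone), the defensin gene Defa24 (-2.71) and Guca2b (-2.13) among the lower ones, and Mmp7 (1.88, named after its value was seen) rising. The Paneth list call (median -1.60, camera adjusted p = 0.0179, and adjusted p = 0.581 with an estimated correlation) ended without Apc_KO replicate 2 (median -1.17), with quantile normalization (-1.61) and with the 5 FPKM filter (-1.38).

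Fetal-like and regenerative genes rose in 11 of 15 cases, with 1 lower and 3 not passing (12 called when adjusted over the list alone). Clu, which marks regenerating epithelium, rose from 27.5 ± 12.5 to 1126 ± 662 FPKM (log2 fold change 5.22, adjusted p = 5.39e-05). Birc3 (-0.68, named after its value was seen) fell. BMP and TGF-beta genes rose in 11 of 19 cases, with Id2 up by 2.04 (locus 73.2% of the gene) and Tgfb1 up by 2.03, while Bmp2 (-1.19, named after its value was seen) fell (12 called when adjusted over the list alone). Interferon response genes rose in 11 of 18 cases and 0 fell (11 called when adjusted over the list alone), including Usp18 (2.01) and Zbp1 (1.83). Camera called all 3 lists higher, fetal-like at adjusted p = 0.000227, BMP and TGF-beta at 0.00432 and interferon at 0.00494. The adjusted p with an estimated correlation was 0.319, 0.319 and 0.393 in that order. With the filter of 5 FPKM the BMP and TGF-beta and the interferon calls ended (medians 0.40 and 0.75, against 1.41 and 0.89).

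All 7 MHC class II genes fell, and 7 were called when adjusted over the list alone. H2-Aa fell from 43.2 ± 13.2 to 9.08 ± 2.58 FPKM and H2-Ab1 from 118 ± 36.6 to 27.6 ± 9.57, the locus of H2-Ab1 spanning 53% of the gene (list median -1.73, camera adjusted p = 0.000113, and adjusted p = 0.319 with an estimated correlation). Markers of other cell types were measured beside these. Of 10 leukocyte genes only the integrin gene Itgam (-1.63) was called, lower (1 called when adjusted over the list alone, list median -0.38, camera adjusted p = 0.0955). Fry called the leukocyte list lower, as did camera without Apc_KO replicate 2 (median -0.61), and the median was -0.08 without Apc_KO replicate 1 or Apc_WT replicate 4. Of 7 stroma and endothelium genes 5 rose, 1 fell and 1 did not pass, with Cdh5, an adhesion gene of endothelium, rising from 0.00395 ± 0.00789 to 22.7 ± 7.07 FPKM and Pdgfra (locus 31.2% of the gene) by 3.93 (6 called when adjusted over the list alone, median 2.54, camera adjusted p = 0.0114, and adjusted p = 0.319 with an estimated correlation). With the 5 FPKM filter the stroma call and the tuft call ended, though the medians were farther from 0 (3.37 and -1.68, against 2.54 and -1.20).

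Cell cycle genes read unevenly between the Apc_KO libraries. The S phase and mitosis median per library, as log2(FPKM + 1), was 3.79, 4.97, 5.00 and 4.24 in Apc_KO replicates 1 to 4 and 4.87, 4.71, 4.84 and 4.63 in Apc_WT (two-sided exact permutation p = 0.486). Of 41 S phase and mitosis genes 4 fell and 37 did not pass (3 called when adjusted over the list alone), with log2 fold changes of -1.66 for E2f2 and -1.40 for E2f8, and Kif23 (42.7 ± 7.45 to 21.9 ± 8.63 FPKM) and Mki67 (53.7 ± 9.47 to 34.1 ± 12.9), which were named after their values were seen. Top2a, a mitotic topoisomerase gene named after its values were seen, read 49.8, 141, 147 and 53.8 FPKM in Apc_KO replicates 1 to 4 against 96.5 ± 17.0 in Apc_WT, and Olfm4 read 106, 674, 702 and 81.7. Camera called the list lower (median -0.16, adjusted p = 0.0242, and adjusted p = 0.794 with an estimated correlation). That call ended without Apc_WT replicate 3 (median -0.10), without Apc_KO replicate 1 (0.09) or 4 (-0.08), with quantile normalization (-0.24), with the 5 FPKM filter (-0.16) and with fry, and turned to 0.22 with arrayWeights. Without Apc_KO replicate 2 the S phase and mitosis median was -0.33 and without replicate 3 it was -0.36. Among p53 targets and cell cycle inhibitors 5 rose, 5 fell and 7 did not pass (12 called when adjusted over the list alone, camera adjusted p = 0.932), with Cdkn1c up by 2.84 and Phlda3 by 2.63.

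Genes of the DNA methylation machinery, named in the study's purpose, were 6 higher, 1 lower and 14 not passing (6 called when adjusted over the list alone, camera adjusted p = 0.46). Dnmt1, the maintenance methyltransferase, was 49.4 ± 13.7 FPKM in Apc_WT and 41.2 ± 16.8 in Apc_KO and did not pass (log2 fold change -0.31, adjusted p = 0.364). Apc_KO replicates 1 to 4 read 25.4, 52.3, 58.8 and 28.3 FPKM for Dnmt1, and the log2 fold change ran from -0.51 without Apc_KO replicate 3 to -0.11 without Apc_KO replicate 1, without a call. Gadd45b rose by 1.22 and Gadd45g by 1.06. Of 20 Polycomb genes 9 rose and 0 fell (9 called when adjusted over the list alone), with Phc1 up by 1.07 and Cbx2 by 0.91 (list median 0.35, camera adjusted p = 0.0415, and adjusted p = 0.319 with an estimated correlation). The Polycomb call ended without Apc_KO replicate 2 (0.32) or 3 (0.33), with size factors (0.24) and with loci of at least 80% of the gene (0.28).

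The remaining lists were as follows. Notch pathway genes were 4 higher and 4 lower of 16 (8 called when adjusted over the list alone, camera adjusted p = 0.46), with the ligand gene Jag2 up by 2.39 and the target gene Nrarp down (-2.31), and fry gave the list the other direction from its median without a call. Nucleolus and polyamine genes were 4 higher of 18 (4 called when adjusted over the list alone, camera adjusted p = 0.194), including Ppat (0.83) and Nop56. Glycolysis genes were 5 higher and 3 lower of 15 (8 called when adjusted over the list alone, camera adjusted p = 0.93), with Slc2a1 up by 1.63 and Pkm by 1.15. Cholesterol synthesis genes were 7 higher of 18 (7 called when adjusted over the list alone, camera adjusted p = 0.208), with Fdps at 0.78 and Mvd at 0.77. The Fdps call ended with size factors (0.66), in a fit of only the 2 genotypes, and without Apc_WT replicate 1 (0.66), 2 (0.77) or 4 (0.76) or Apc_KO replicate 2 (0.59), 3 (0.75) or 4 (0.71). Immediate early and heat shock genes were 2 higher of 13, Ier3 (2.47) and Atf3 (1.87, locus 27.4% of the gene) (2 called when adjusted over the list alone, camera adjusted p = 0.358).

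Regional markers of the intestine were lower for the proximal small intestine, 4 of 6 falling and Cybrd1 (1.40, named after its value was seen) rising (6 called when adjusted over the list alone). Adh6a fell by 3.25 and the homeobox gene Pdx1 had a log2 fold change of -1.43 (list median -1.24, camera adjusted p = 0.0385, and adjusted p = 0.382 with an estimated correlation). That list call ended with size factors (-1.34), quantile normalization (-1.49) and without Apc_KO replicate 2 (-1.19), 3 (-1.19) or 4 (-1.17). Ileum and colon genes were 3 higher and 4 lower of 9 (7 called when adjusted over the list alone, camera adjusted p = 0.456), with Bex1 at 5.68 and Car4 at -4.40; the list's median was -0.69 and its mean 0.07, and the median was -0.25 without Apc_WT replicate 3. In total camera called 15 of the 26 lists, 6 higher and 9 lower, fry 20, and camera with an estimated correlation 0.

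**Figure D2:**
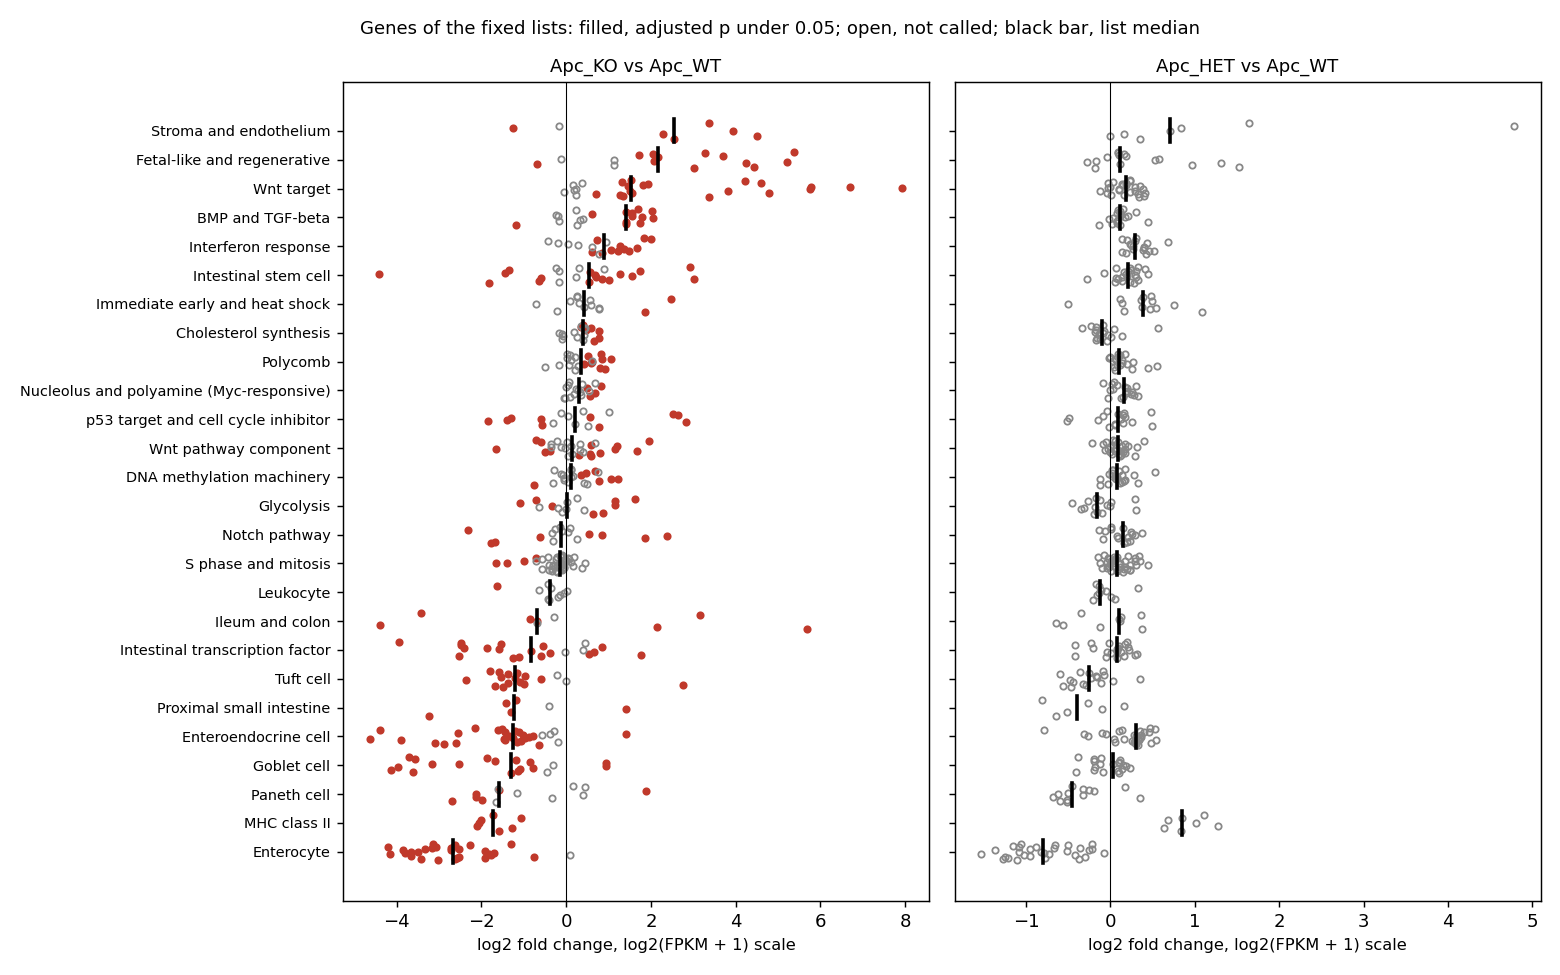
Log2 fold change of each kept gene of the fixed lists (points; filled, called; open, not called) for Apc_KO against Apc_WT and Apc_HET against Apc_WT, with list medians as black bars. The enterocyte median was -2.68 in Apc_KO and -0.80 in Apc_HET, and no point is filled for Apc_HET.

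The comparison of Apc_HET with Apc_WT asks what loss of 1 Apc copy did. No single gene passed the limma test. All 7 MHC class II genes, which present antigen, had higher values in Apc_HET: Cd74 averaged 542 ± 237 FPKM (SD, n = 4) against 288 ± 65.5, and H2-Ab1 253 ± 131 against 118 ± 36.6 (log2 fold change 1.02, SE 0.36, adjusted p = 0.987). Those 7 of 7 were called when adjusted over the list alone, against 0 over all genes, with a list median of 0.85. The MHC class II median per library was 6.63, 6.53, 7.69 and 5.89 in Apc_HET replicates 1 to 4 and 4.75, 5.43, 5.61 and 5.87 in Apc_WT, and that of Wnt targets 3.57, 3.60, 3.51 and 3.47 against 3.39, 3.36, 3.27 and 3.31. Each had the smallest two-sided exact permutation p, 0.0286, and 0.330 adjusted over lists. These library medians are of the values as deposited, in which the median log2 fold change of all genes was 0.066. With size factors that of all genes was 0.00012. The MHC class II median of Apc_HET replicate 4, 5.89, was over the 5.87 of Apc_WT replicate 4 by less than that shift of 0.066. The permutation test was not run on scaled values, so the full separation of the MHC class II medians may rest on the scaling. Enterocyte genes had lower values, with a list median of -0.80 and Lct, the lactase gene, at 9.18 ± 5.40 against 23.9 ± 11.4 FPKM (0 called when adjusted over the list alone). The enterocyte median per library, as log2(FPKM + 1), was 6.33, 5.24, 4.84 and 6.42 in Apc_HET replicates 1 to 4 and 6.10, 6.23, 6.36 and 7.18 in Apc_WT, so only Apc_HET replicates 2 and 3 lay under the Apc_WT libraries (two-sided exact permutation p = 0.257). Axin2 was 65.9 ± 7.54 against 49.6 ± 6.29 FPKM (log2 fold change 0.40, adjusted p = 0.987), Lgr5 26.4 ± 4.52 (0.14) and Dnmt1 52.3 ± 2.88 (0.12), none passing. The Dnmt1 value was -0.01 without Apc_WT replicate 4, which turned its direction, 0.06 without 2 and 0.29 without 3. That of Lgr5 was 0.25 without Apc_WT replicate 1, 0.07 without 3, 0.05 without Apc_HET replicate 3 and 0.23 without 4.

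**Figure D3:**
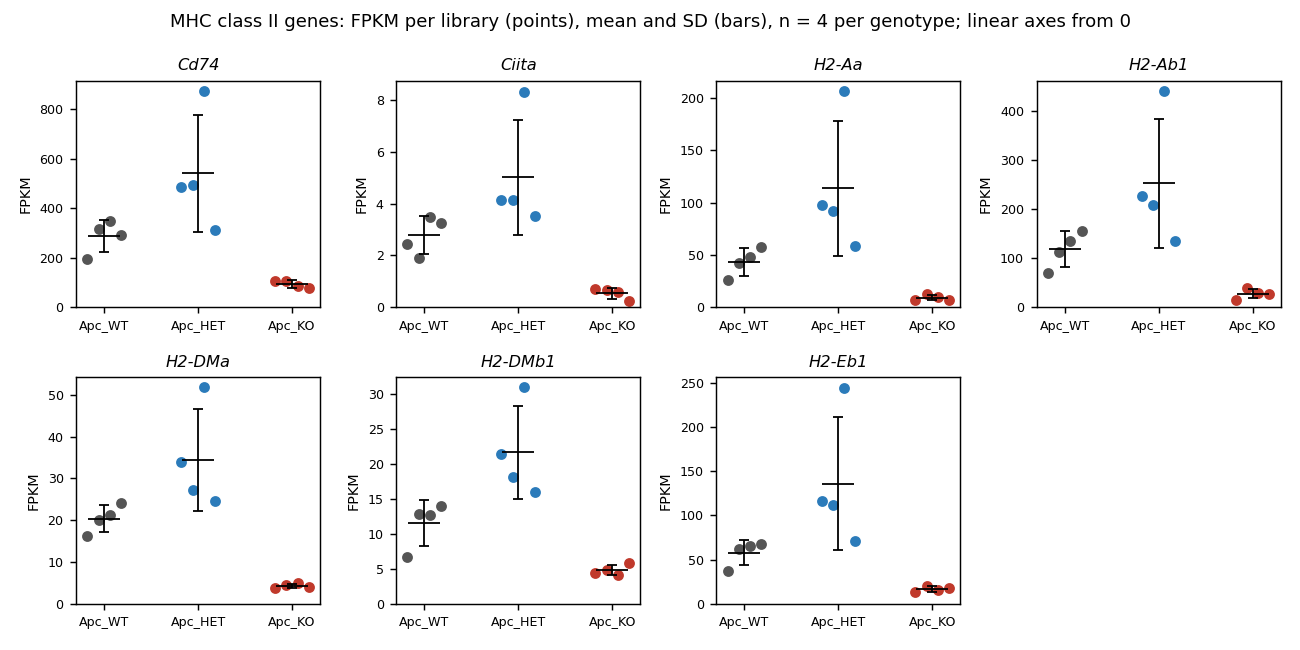
FPKM of the 7 measured MHC class II genes in each library (points) by genotype, with the mean and SD (bars, n = 4) on linear axes from 0. Cd74 averaged 288 FPKM in Apc_WT, 542 in Apc_HET and 94.1 in Apc_KO.

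Of 12962 genes limma called 0, with 561 (4.33%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.119, and 95% of genes had an absolute log2 fold change under 0.52. Of all genes, 6.08% had no overlap between the libraries of Apc_HET and Apc_WT, against 2.86% by chance. That share was taken from the values as deposited, and none was computed under another scaling. The size factors did not overlap either, at 0.953 to 0.964 in Apc_WT and 1.01 to 1.02 in Apc_HET. Scaling alone can therefore raise the share over that by chance. In the simulated test of Apc_HET against Apc_WT, 85 of 100 genes of log2 size 1 were recovered. Those genes lay above a minimum level in Apc_WT and had independent noise, so the share may be lower in the real libraries. H2-Ab1, with a fold change of about that size, did not pass. The smallest unadjusted p among genes with higher values under the rule belonged to Pou4f1 (2.08, locus 16.7% of the gene), Pcf11 (0.42) and P4ha2 (1.17), and among those with lower values to Tmprss15 (-2.11, locus 0.311% of the gene), Lct (-1.37) and Slc7a15 (-1.26, locus 18.2% of the gene). Adding 0.1 in place of 1 FPKM, fitting only the 2 genotypes, or arrayWeights called 1 gene, Mdga1 (locus 0.235% of the gene), named after its value was seen. Without Apc_WT replicate 3 there were 3 calls, without Apc_HET replicate 4 there were 4, and without Apc_KO replicate 2 there was 1.

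Camera called 14 of 26 lists in Apc_HET, 8 higher and 6 lower, camera with an estimated correlation 0 and fry 0. For MHC class II the adjusted p was 6.45e-10, and adjusted p = 0.275 with an estimated correlation, and for enterocytes 7.05e-27, and adjusted p = 0.275 with an estimated correlation. Stroma and endothelium had a median of 0.70 with camera adjusted p = 0.00198, and adjusted p = 0.294 with an estimated correlation, and 1 gene, Vim, was called when adjusted over the list alone (44.1 ± 29.2 against 11.6 ± 5.48 FPKM). Interferon response (0.30), Wnt target (0.19), stem cell (0.21), enteroendocrine (0.30), Polycomb (0.10) and immediate early and heat shock (0.39) lists, with their medians, were the others called higher. Tuft cell (-0.25), Paneth cell (-0.45), proximal small intestine (-0.39), glycolysis (-0.16) and cholesterol synthesis (-0.10) lists were the others called lower, and in these 11 lists 0 genes were called when adjusted over the list alone. Their adjusted p with an estimated correlation ran from 0.294 for proximal small intestine to 0.776 for enteroendocrine genes. Of the 14 calls, 7 held without each library in turn, and without Apc_WT replicate 3 only 9 lists were called. The goblet (median 0.03, mean -0.03) and ileum and colon (0.10, -0.06) lists differed in sign between median and mean and were not called, and intestinal transcription factors (0.08) and p53 targets and cell cycle inhibitors (0.10) had positive medians and a lower direction by camera, without a call.

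Single libraries moved many of these Apc_HET list values. Tuft cell genes had a median of -0.45 without Apc_HET replicate 2 and -0.14 without 4, Paneth cell genes -0.25 without Apc_HET replicate 3, proximal small intestine genes -0.22 without Apc_WT replicate 4, and glycolysis genes -0.10 without Apc_WT replicate 4 and -0.09 without Apc_HET replicate 3. For cholesterol synthesis it was 0.01 without Apc_WT replicate 3, which ended the call, -0.17 without 1 and -0.16 without 2. The interferon response call ended without Apc_HET replicate 3 (0.17). Stem cell markers lost theirs without Apc_WT replicate 3 (0.20) or 4 (0.18) or Apc_HET replicate 2 (0.19) or 3 (0.14). Wnt targets lost theirs without Apc_WT replicate 2 (0.14) or 3 (0.22) or Apc_HET replicate 2 (0.14) or 3 (0.15). Immediate early and heat shock genes lost theirs without Apc_WT replicate 3 (0.22), Apc_HET replicate 1 (0.33), 2 (0.38) or 3 (0.21) or Apc_KO replicate 1 or 4 (0.39 each), and had 0.65 without Apc_HET replicate 4. Enteroendocrine genes kept a call without Apc_WT replicate 4 (0.51) but not without Apc_WT replicate 1 (0.21), 2 (0.27) or 3 (0.24), Apc_HET replicate 1 (0.28), 3 (0.24) or 4 (0.33) or Apc_KO replicate 1 (0.30). Polycomb genes lost theirs without Apc_WT replicate 1, 3 or 4 (0.11 each), Apc_HET replicate 1 (0.12), 2 (0.10) or 3 (0.10) or Apc_KO replicate 4 (0.10).

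The 2 effects were compared across genes, which are not independent replicates. With separate Apc_WT libraries for each effect, the covariance was 0.0570, the correlation 0.163 and the slope of the Apc_HET effect on the Apc_KO effect 0.0533 (SD 0.0148 over 6 splits), against a covariance of -0.000827 in simulations without change. With shared controls the covariance was 0.0833, against 0.0320 in simulations without change. The simulations drew independent noise for each gene, so they give no background for libraries whose genes vary together. The 6 splits reuse the same libraries, so their SD is not a sampling error. The slope was 0.0233 without Apc_HET replicate 3 and 0.0822 without Apc_HET replicate 4.

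The comparison of Apc_KO with Apc_HET asks what loss of the second copy added. Notum was 0.204 ± 0.0851 FPKM (SD, n = 4) in Apc_HET and 303 ± 49.9 in Apc_KO (log2 fold change 7.97, SE 0.13, adjusted p = 5.53e-12), and Nkd1, another Wnt feedback gene, rose from 0.962 ± 0.305 to 99.0 ± 23.1. Olfm4 fell by 4.60 on the log2 scale from 6301 ± 1328 FPKM, and Cps1, a urea cycle enzyme gene, fell by 4.26, and Gcg, the glucagon gene, fell by 4.45. H2-Aa fell by 3.39, from 113 ± 64.1 to 9.08 ± 2.58 FPKM. Axin2 rose by 0.94 (adjusted p = 0.000204), Lgr5 (0.56, adjusted p = 0.0734) and Dnmt1 (-0.43, adjusted p = 0.214, from -0.62 without Apc_KO replicate 3 to -0.23 without Apc_KO replicate 1) did not pass. An Lgr5 call was gained in 3 settings, among them without Apc_KO replicate 4 (0.73) and with arrayWeights (0.47), and without Apc_KO replicate 1 the value was 0.31.

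Limma called 5413 of 12962 genes, 2960 higher and 2453 lower, of which 1338 and 998 by at least 2-fold, and 39.5% of genes had no overlap against 2.86% by chance. Of the genes called in both comparisons with Apc_KO, 2820 were higher in both (825 by chance) and 2048 lower in both (434 by chance), with 0 opposite. With the Apc_KO libraries divided so that none served both, these were 2065 (684 by chance), 1519.5 (369 by chance) and 27 on average over 6 splits. Wnt targets rose in 19 of 25 cases, and fetal-like genes in 11 of 15, with Clu up by 5.49. Enterocyte genes fell in 25 of 30 cases, including Sis (-3.32), enteroendocrine genes in 24 of 29, goblet genes in 16 of 19, including Clca3 (-3.95), and all 7 MHC class II genes fell. Avil rose by 3.06 and Defa24 fell by 2.12. Ileum and colon genes had a median of -0.41 and a mean of 0.14 and were not called, with a median of -0.20 without Apc_KO replicate 4.

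Other named genes in this comparison were the receptor gene Fzd5 (-1.84), Jag2 (2.31), E2f2 (-1.54), Gadd45g (1.18), Phc1 (1.01), Srm (0.77), Pkm (1.41), Fdps (0.94), Cdkn1c (2.58), Id2 (2.01), Usp18 (1.87), Ier3 (2.36), Itgam (-1.49), Cdh5 (4.51), Adh6a (-2.61) and Bex1 (5.31). The Srm call ended in a fit of only the 2 genotypes and without Apc_HET replicate 3 (0.66) or 4 (0.71) or Apc_KO replicate 2 (0.58), 3 (0.67) or 4 (0.76). Counts adjusted over the list alone were 19 Wnt target, 12 fetal-like, 27 enterocyte, 25 enteroendocrine, 18 goblet and 7 MHC class II genes. Camera called 13 lists, 6 higher and 7 lower, fry 13, and camera with an estimated correlation 0. The smallest adjusted p with an estimated correlation was 0.361, for Wnt targets, against 2.56e-10 at the preset. Of the 13 calls, 9 held without each library in turn; 4 did not. Cholesterol synthesis genes lost their call without Apc_HET replicate 2 (0.45) or 4 (0.51), Apc_KO replicate 2 (0.34) or 3 (0.44) and with fry, and interferon response genes without Apc_HET replicate 4 (0.48), Apc_KO replicate 2 (0.59) or 3 (0.55) and with the 5 FPKM filter (0.44). S phase and mitosis genes lost theirs without Apc_KO replicate 1 (-0.04) or 4 (-0.19), with fry and with arrayWeights (0.10), and had -0.47 without Apc_KO replicate 2 or 3. Stroma and endothelium genes lost theirs without Apc_KO replicate 1 (2.16), with arrayWeights (2.19) and with the 5 FPKM filter (1.72), and tuft cell genes with that filter (-1.12).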

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

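The rule for single libraries in this part was set before the data were examined, and it was applied to 110 genes that the named-gene rule had picked from the results. In each genotype, the gap between the highest or lowest library and its nearest neighbour was divided by the range of the group, for the named genes on the log2(FPKM + 1) scale and for library totals, and values above Dixon's 95% critical value are listed. There were 21 among 342 groups, and chance gives about 1 in 20, here 17.1. No biological explanation was tested for any of them.

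Agr2 was lowest in Apc_KO replicate 1 at 5.78 against 7.03 to 7.25 in the others (0.851). Gadd45g in the same library was highest, 7.33 against 6.89 to 6.93 (0.904). Postn there was 6.42 with the others listed at 0 (1). In Apc_KO replicate 2, Slc1a1 was 7.62 against 0 to 0.21 (0.972). Apc_KO replicate 4 was highest for Avil, 6.75 against 5.76 to 5.92 (0.846), and for Guca2b, 4.90 against 4.46 to 4.53 (0.853). It was lowest for Jun, 9.28 against 9.87 to 9.96 (0.856).

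Bex1 was lowest in Apc_WT replicate 1, 0.57 against 1.24 to 1.34 (0.866), and Pdgfra was 0.08 there with the others at 0 (1). Cdh5 was 0.02 in Apc_WT replicate 2 with the others at 0 (1), and Csnk1a1 was lowest in it, 7.12 against 7.33 to 7.35 (0.898). Postn was 7.07 in Apc_WT replicate 3 with the others at 0 (1). Fabp1 was highest in Apc_WT replicate 4, 10.25 against 8.65 to 8.82 (0.894), as was Msx1, 0.52 against 0.25 to 0.30 (0.841). Loci that name no gene held 9.67% of FPKM in Apc_WT replicate 2 against 1.01 to 1.76% in the others (0.914).

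Csnk1a1 was lowest in Apc_HET replicate 3, 7.37 against 7.42 to 7.43 (0.942), and Sox17 highest, 0.03 against 0.01 (0.951). Apc_HET replicate 4 was lowest for Msx1, 0.09 against 0.51 to 0.57 (0.879), and for Postn, at 0 against 8.11 to 9.43 (0.861). It was highest for Onecut2, 3.98 against 3.61 to 3.65 (0.893). Its total was 411679 FPKM against 439235 to 440254 (0.964).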

How the results depend on the processing

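Tests named as added were chosen after the data were seen. Of the values that answer a comparison, 185 were the same under an alternative, 11 weaker, 8 stronger and 3 moved, with counts taken as the same within 1.5 times. Of those for single genes 3813 kept their direction and side of the threshold, 20 lost their call and 4 gained one, and of those for single lists 1817, 177 and 26, with 2 in the other direction. The cause of the changes below was not tested, except where a setting tests fewer genes or libraries.

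A 2-fold minimum left 2568 of 5904 genes for Apc_KO against Apc_WT and 2336 of 5413 for Apc_KO against Apc_HET, by its construction. Apc_HET against Apc_WT had 1 gene called, Mdga1, with a pseudocount of 0.1, in a fit of only the 2 genotypes and with arrayWeights. Leaving out 1 library gave 0 to 4 genes there, 5244 to 6269 for Apc_KO against Apc_WT and 4562 to 5622 for Apc_KO against Apc_HET. The replicate number as a block gave 5681, 0 and 5178 genes and 15, 11 and 13 lists in the order Apc_KO against Apc_WT, Apc_HET against Apc_WT, Apc_KO against Apc_HET, and called Lgr5 in the last of these (0.56). The rule for pairing asked for every pair of equal numbers over a correlation of 0.1 and was not met. Of the 4 pairs of Apc_KO with Apc_WT 3 were over it (0.180, -0.103, 0.120 and 0.150 for replicates 1 to 4), and of the 8 other pairs 0, the lowest at -0.195. The best partner had the same number in 3 of 12.

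Lists called for Apc_KO against Apc_WT were 9 with the 5 FPKM filter, and 13 to 15 without 1 library. Those of Apc_HET against Apc_WT were 9 to 14 without 1 library, 0 with fry, and those of Apc_KO against Apc_HET 11 to 13. Camera with an estimated correlation called 0 in each comparison, as did the added exact permutation test of library medians, whose adjusted p was at least 0.0531 for Apc_KO against Apc_WT with 14 lists at the smallest possible p. The S phase and mitosis list turned to 0.22 with arrayWeights, and the ileum and colon list, at -0.69, was called in the other direction by fry. For Apc_KO against Apc_WT fry also called the stem cell, Wnt pathway component, DNA methylation and p53 target lists higher and the leukocyte list lower, none of them called by camera. Robust eBayes was not run on lists, since camera has no such option.

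The Apc difference without 1 library ran from 0.47 to 0.71 for Apc_KO against Apc_WT, 0.19 to 0.37 for Apc_HET against Apc_WT and 0.17 to 0.42 for Apc_KO against Apc_HET. The slope was 0.0696 over called genes and, added, 0.0233 to 0.0822 without 1 library. Added settings with the highest locus of each symbol gave 5884, 0 and 5376 genes, and with loci of at least 80% of the gene 4854, 0 and 4436 of 10376. Depth is unknown, so what it limits could not be stated.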

Other observations

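Gene families were grouped by symbol after the data were seen, 20 of them, and all tests in this part were chosen after the results were seen, except the alternatives planned before. In Apc_KO against Apc_WT all 10 carboxylesterase genes fell (median -3.31), including Ces1f from 43.7 ± 19.3 to 1.19 ± 0.970 FPKM (SD, n = 4), as did 6 of 7 UDP-glucuronosyltransferase genes (median -1.04). Of 41 cytochrome P450 genes 20 fell, 9 rose and 12 did not pass, and of 12 glutathione S-transferase genes 7 fell, 2 rose and 3 did not pass. All 5 butyrophilin-like genes fell (median -2.80), among them Btnl1 from 35.2 ± 10.1 to 1.64 ± 0.958 FPKM. Of 41 complex I genes 7 fell and 0 rose. Of all 12962 genes 2291 fell and 3613 rose, so the share that fell was similar. Of 8 Sox genes 6 rose (median 1.62), of 6 insulin-like growth factor binding genes 4 rose (median 3.10), and 5 of 5 Hox symbols rose, an antisense transcript of Hoxb3 among them, 2 of 5 with quantile normalization. With size factors and quantile normalization carboxylesterase and butyrophilin-like counts stood at 10 and 5, and complex I at 14 and 16 lower. Camera's adjusted p was 5.88e-07 for carboxylesterases, 7.11e-05 for butyrophilin-like, 0.00184 for Sox, 0.00256 for insulin-like growth factor binding, 0.00245 for P450 and for UDP-glucuronosyltransferase, 0.00091 for complex I, 0.0988 for Hox and 0.0118 for glutathione S-transferase genes. In that order the adjusted p with an estimated correlation was 0.302, 0.302, 0.356, 0.302, 0.449 and 0.337, 0.609, 0.449 and 0.521.

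Some loci read very unevenly between libraries of a genotype. Cav1 was 0.0833, 0.225, 1600 and 941 FPKM in Apc_WT replicates 1 to 4 and 4741, 8267, 842 and 0 in Apc_HET, and 1.17, 0.219, 0.783 and 0.185 in Apc_KO. The Postn locus spans 3.90% of the gene, that of Col6a1 4.03%, that of Hand2 45.6% and that of Cd3d 24.3%. Epcam, an epithelial gene, averaged 791 ± 63.2, 767 ± 12.5 and 791 ± 215 FPKM (SD, n = 4) in Apc_WT, Apc_HET and Apc_KO. It read 649, 721, 685 and 1110 in Apc_KO replicates 1 to 4.

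For the called genes, other splits of the 8 libraries into 4 and 4 called few or none. For Apc_KO against Apc_WT 1 of 35 splits was as large (highest other 0 against 5904). For Apc_KO against Apc_HET it was also 1 of 35 (highest other 3 against 5413). Splits that mix the genotypes place their difference in the spread, which lowers the counts, and 1 of 35 is the smallest share possible. These splits therefore do not exclude chance by themselves. For Apc_HET against Apc_WT, with 0 genes called, every split calls as many (35 of 35, highest other 3), so the splits say nothing there. For the list counts chance is not excluded: 3 of 35 splits reached the 15 of Apc_KO against Apc_WT (highest other 15), 2 of 35 the 14 of Apc_HET against Apc_WT (15) and 7 of 35 the 13 of Apc_KO against Apc_HET (15). Splits with unequal numbers of the 2 genotypes on a side carry part of the genotype difference, so these counts do not show that chance made the calls.

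Genes of the 5 differentiated cell type lists were lower in Apc_KO. Scaling between libraries moves all genes of a library alike, and is argued against as the whole cause: the median of the 108 members lay under that of all genes by a log2 difference of -1.72 (SE 0.0993) in the scaling where it was smallest. Each SE in this paragraph comes from resampling list members, not libraries, so it holds no spread between mice. The members also varied together, with estimated correlations from 0.206 for goblet to 0.636 for enteroendocrine genes. An earlier count of members that stayed called lower was dropped, since both scalings shift genes that way. The list medians differed by up to 1.48 on the log2 scale (SE 0.261), from -2.68 for enterocytes to -1.20 for tuft cells. This does not decide on one equal loss of every other cell type from the sort. Such a loss need not lower all lists alike where the stem cells also express some of their genes. The pair was also picked as the lowest and highest median, which the SE does not cover. Separate changes in the share of each cell type, with 5 of 108 members called higher, cannot be told apart from less RNA per cell in bulk libraries. Values of single cells would be needed to decide it.

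MHC class II genes were higher in Apc_HET by a list median of 0.85. Leukocytes among the sorted cells are not excluded. Cd3d of the fixed leukocyte list was higher by 20.02 FPKM, over the limit of 5% of the 253 of Cd74, and the other 13 leukocyte genes in the tables by at most 1.08. The first form of the test held only 8 genes chosen after the data were seen, 6 of them in the tables, with 0.412 as the largest difference, and was widened to the list later. Cd3d read 0.428, 125, 0.502 and 63.9 FPKM in Apc_HET replicates 1 to 4 and 15.2, 0, 67.6 and 27.1 in Apc_WT, through a locus of 24.3% of the gene. It was low in Apc_HET replicate 3, where Cd74 was highest, so it does not decide the question. Among the added genes Ptprc, Coro1a, Cd79a and Itgax were highest within Apc_HET in replicate 3, at 2.15 FPKM or less, while Laptm5 and Cd79b were not. Of the fixed list, Gzma was also highest there, at 9.12, 8.01, 19.4 and 6.02 FPKM in Apc_HET replicates 1 to 4. It read 10.6, 8.44, 5.93 and 22.1 in Apc_WT, however, and Itgam was lowest in Apc_HET replicate 3, at 2.37 FPKM. The leukocyte list had a median of -0.12 and no call. That median was 0.14 without Apc_WT replicate 4 and 0.02 without Apc_HET replicate 4, which turned its direction, -0.07 without Apc_HET replicate 1, and was called lower without Apc_WT replicate 2 (-0.13) or Apc_HET replicate 3 (-0.14). Apc_HET replicate 3 alone is argued against by a median of 0.67 without it, and scaling by one of 0.78 at the lowest. Other cell types in the sort stay open and were not tested. In Apc_HET replicates 1 to 4 Cd74 read 486, 493, 875 and 313 FPKM, against at most 347 in Apc_WT, and stromal genes were also lowest in replicate 4, with Vim at 42.4, 82.5, 40.1 and 11.5, Pdgfra at 0.767, 1.17, 0.642 and 0.181 and Postn at 276, 401, 688 and 0. No gene passed over all genes.

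Stroma and endothelium genes were higher in Apc_KO. Scaling as the whole cause is argued against by a median of the 7 members that lay over that of all genes by 2.39 at the lowest (SE 1.15), little more than 2 SE. That SE also comes from resampling the members, not the libraries, so it holds no spread between mice. Whether stromal or endothelial cells were in the sort cannot be told apart from expression in the stem cells: only Col1a1 of the 7 collagen and endothelial genes was in the tables, at 1.46 FPKM against 22.7 for Cdh5, through a locus of 9.16% of the gene, and the rule was changed from exclusion once that was seen. Other genes of such cells were looked at after their values were seen and went both ways. Col4a1 rose from 0.0254 ± 0.00824 to 4.06 ± 1.10 FPKM, a level below that of Cdh5, while Cav1, with a locus of 93.8% of the gene, was 0.589 ± 0.473 FPKM in Apc_KO but uneven in the other genotypes. Such a share of cells stays undecided.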
